A study of Mus musculus with 3 samples.

How the data were processed

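Epithelium was separated from mouse corneas with an enzyme and dissociated with trypsin, and single cells were made into 3 libraries with the 10x Chromium Next GEM 3′ v3.1 kit, as the labels state. Per the labels, Cell Ranger 5.0.0, Seurat 4 and the mouse genome build mm10 were used, with no role or order given for them. Filters on cells and genes, the handling of doublets and the annotation release are not given in the sources used here. The deposited matrix held raw UMI counts per gene and cell, with no normalisation by the authors, as whole numbers from 0. A deposited metadata table gave, for each cell, the name of its library and the cell type label of the authors. How the labels were made is not given in the sources used here, and their abbreviations are not spelled out. LSC was read as limbal, Squam as superficial and Conj as conjunctival, and each reading rests on the markers in the text. Libraries 2 and 3 were matched to the labels by the number in their names and library 1 by elimination, with 0 columns left over. Xist and Y-linked genes bear on library 2 alone, since libraries 1 and 3 are both from males. Pairs of libraries differed over genes by a chi-square per degree of freedom of 80.4, 152 and 222, so no pair held the same counts.

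Cells of each library and class were summed, and 6 pairs of classes were compared. These were limbal, superficial, wing, cycling and conjunctival cells each against the basal class, and superficial against wing cells. TAC1 and TAC2 were summed as cycling cells. All 7 epithelial classes are in these pairs, so a comparison of each class with the mean of the others, planned for classes in no pair, was not needed. The immune class was in no planned comparison, and its share of dividing cells is not given, since libraries 1 and 3 held 16 and 5 of its cells at 2000 UMIs, fewer than the 20 required. Both classes of a pair came from the same 3 libraries, so the library was a block in the model, as a pairing by construction. The test was the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3, TMM scaling, filterByExpr, robust fit). Adjusted p are by Benjamini and Hochberg within a comparison, with a threshold of 0.05. CPM beside fold changes are scaled by TMM over the pair of classes compared, and CPM in the account of the markers are a class's counts scaled to its own total. Fold changes are log2 with the standard error of the fit. Errors of means are SD over 3 libraries.

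Before the data were examined 31 gene lists with 494 genes, 16 sets of cell type markers with 95 genes, the comparisons, their tests and most alternatives were fixed. Of the 494 genes 477 were in the table, and of the 95 markers 71. The others were not analysed here. The lists were tested with camera (limma 3.58.1) on voom values of the same sums, with a preset correlation between genes of 0.01, and adjusted over the 186 tests of 31 lists and 6 comparisons. With the preset correlation 64 tests passed, and with a correlation estimated from the data 0 did, with a lowest adjusted p of 0.614. With an estimate, camera tests on the residual degrees of freedom, which are few for 6 sums with a library block. Even the G2 and M phase list of cycling cells, with all 26 genes higher, had 0.614. This alternative could hardly pass any list, so its values do not weigh against a list. The rotation test fry, which asks whether a list's genes move on balance in 1 direction, passed 127. A count within a list is of genes past the threshold over all genes tested, and beside it that adjusted over the list alone.

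The genes named in the text follow a rule that was also fixed before the data were examined. For each comparison it takes the 10 largest higher and the 10 largest lower log2 fold changes with adjusted p under 0.05, the same sign in every library and a mean log2 CPM of at least 5. Cell type markers, mitochondrial genes, ribosomal protein genes and predicted genes without a proper name are left out. Of each list described it takes up to 4 members, the 2 most abundant and the 2 with the largest absolute fold change among those past the threshold. It further takes the markers, Xist and Y-linked genes, and Sparc. Some genes that the rule takes are not reported here. Genes were matched by symbol to GENCODE M21 on GRCm38, in which 17641 of the 17931 symbols were found and 290 were not. The kit reads 3′ ends, so genes with near-identical copies, such as Ftl1, histone, ribosomal protein and class I genes, share reads, and their values are uncertain.

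Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 allows up to 3 counts of the total. For dividing cells and genes per cell every cell was thinned at random to 2000 UMIs, which left out 609 cells with fewer, among them 233 basal, 187 TAC2 and 58 immune cells. Differences from basal cells in these measures were tested by exact two-sided sign flips over the 3 libraries, which cannot give a p under 0.25. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 and matplotlib 3.10.9 was used.

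The model was tested on simulated data with 200 genes changed. With a dispersion following the trend over expression, between 3.12 and 7.44% of the calls were false in the 6 comparisons. With the dispersion of each gene kept, false calls were 5.10% in limbal, 21.0% in superficial, 14.3% in wing, 14.8% in superficial against wing, 10.5% in cycling and 13.0% in conjunctival cells, so the threshold of 0.05 was exceeded there. No call had the wrong sign, and 0 of 30 unchanged lists were called. Genes were drawn independently of each other, and far fewer were changed than differed in the data. The simulation therefore does not show how the list test behaves with correlated genes, or the scaling with most genes changed. With the trend a change of 1.5 times was found in 49.2% of genes for limbal cells and in 87.9% for cycling cells, and a change of 4 times in 95.4% and 100%. With the dispersion of each gene kept these were 46.0, 86.4, 90.9 and 98.4%.

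Because the classes were made from the same counts, each cell's UMIs were also split in 50% portions. Classes were reassigned from 1 portion by the deposited labels of 30 neighbours over 30 principal components of 2000 variable genes, and tests were run on the other. Those labels were made before the split, so the portion tested may have shaped them, and the reuse of counts is only partly removed. Below, this alternative is called reassigned classes. By the reassignment 91.2% of the cells kept their class, with 75.3% of limbal and 95.2% of basal cells. Further alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 as the test, no library block, leaving out each library, thinning to 2000 UMIs, equal cell numbers, and for the lists an estimated correlation, fry and leaving out class markers. Removing doublets called by Scrublet was planned too, but its own threshold called 0 cells. Chosen after seeing the data were leaving out the highest Scrublet scores (720, 1017 and 2408 cells of libraries 1, 2 and 3, at 0.8% per 1000 cells), leaving out limbal cells with conjunctival keratins, summing basal, TAC1 and TAC2 cells as the reference of limbal cells, TAC1 and TAC2 apart, and 50% of the UMIs with the deposited classes.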

Results

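Single-cell RNA sequencing was done on the corneal epithelium of C57BL/6J mice in homeostasis, with a droplet kit that counts the 3′ ends of transcripts by unique molecular identifiers (UMIs). The 3 libraries formed 1 group. Library 1 came from 4 corneas of 2 male mice aged 20 weeks. Library 2 came from 4 corneas of 2 female mice aged 11 weeks, and library 3 from 7 corneas of 7 male mice aged 10 weeks. The deposited table held 17931 genes and 38111 cells, of which 9488 were in library 1, 11273 in library 2 and 17350 in library 3. The libraries held 187340736, 177449217 and 190393121 UMIs. Median depth per cell was 16159.5 UMIs in library 1, 13232 in library 2 and 8334 in library 3, and the shallowest cell of each held 508, 508 and 510. The median percentage of mitochondrial UMIs was 1.60, 1.56 and 1.75. Xist, the transcript of the inactive X chromosome, had 0 UMIs in library 1, which allows up to 0.0160 CPM (counts scaled to the library's total), 99239 in library 2 and 8 in library 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 5681, 10794, 2253 and 1519 UMIs in library 1 and 6115, 11602, 2500 and 1752 in library 3. All 4 had 0 in library 2, which allows up to 0.0169 CPM each, so every library matched the sex on its label. Age, sex and number of mice differed between the libraries, so values are given per library and no test between libraries was made.

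The deposited annotation put every cell in 1 of 8 classes. These were 737 limbal, 8829 basal, 4136 and 3186 cells of 2 transit-amplifying classes (TAC1 and TAC2), 13447 wing (suprabasal), 5240 superficial, 2422 conjunctival and 114 immune cells. Wing cells were the most numerous class, with 34.7% ± 3.55 of the cells of a library (mean ± SD, n = 3), followed by basal cells with 22.5, 22.8 and 23.7% in libraries 1, 2 and 3. Superficial cells made up 13.4% ± 2.10, conjunctival cells 6.38% ± 0.999 and immune cells 0.331% ± 0.249. The immune share was 0.274, 0.603 and 0.115% in libraries 1, 2 and 3. The limbal share was 1.72% (exact binomial 95% interval 1.47 to 2.00) in library 1, 3.09% (2.78 to 3.42) in library 2 and 1.30% (1.14 to 1.48) in library 3. TAC2 cells had a share of 8.35% ± 0.414. The TAC1 share was 14.1% in library 1 and 14.5% in library 2, and 6.66% (6.30 to 7.04) in library 3. The intervals cover counting error only. The classes were annotated on the same expression values, so the markers that follow describe the classes and do not test them.

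**Figure D1:**
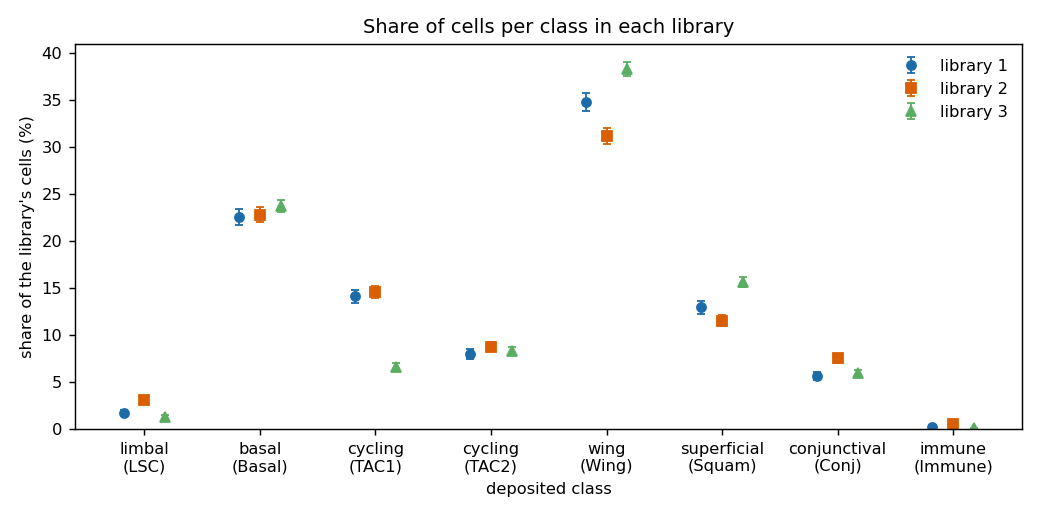
Share of the cells of each library (percent, y axis) in each deposited class (x axis), with 1 point per library and its exact binomial 95% interval. The TAC1 share of library 3, 6.66%, lies below those of libraries 1 and 2, 14.1% and 14.5%.

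Gpha2, a glycoprotein hormone subunit, marked the limbal class, with 2700 ± 135 CPM (mean ± SD over the 3 libraries) against 115 ± 42.2 in basal cells and 88.7 ± 37.7 in conjunctival cells. The tetraspanin Cd63 had 121 ± 2.50 CPM in limbal cells and 1.07 ± 0.534 in basal cells, and its highest mean was in immune cells, 323 ± 187. Krt15, a keratin of limbal basal cells, had its highest mean in the conjunctival class, 25402 CPM, and the next highest in the limbal class, 8912. The basal keratin Krt14 was highest in limbal cells, at 3529 ± 1270 CPM against 590 ± 178 in basal cells. In conjunctival cells Krt14 had 1255 CPM in library 2 and 121 and 58.5 in libraries 1 and 3. Basal cells had the highest mean of Trp63, the p63 transcription factor, at 198 ± 9.02 CPM. Krt5, also fixed as a basal marker, was highest in wing cells, at 10163 CPM against 5639 in basal cells. The hemidesmosome collagen Col17a1 had 1212 ± 108 CPM in basal and 1277 ± 126 in TAC1 cells. Krt12, the corneal keratin, was highest in wing cells (28786 CPM) and had 19846 in basal, 5052 in limbal and 4649 in conjunctival cells. Immune cells had 6125 ± 3225 CPM of Krt12, above the limbal and conjunctival means. Whether free RNA or mixed droplets gave part of these lower values was not tested. Aldh3a1, the corneal crystallin, was highest in basal cells, at 15146 CPM. The membrane mucin Muc4 was highest in superficial cells, at 2270 ± 309 CPM against 10.1 ± 3.45 in basal cells, and Krt78 had 235 ± 9.92 CPM there. Of the other markers fixed as superficial, Ly6g6c (1060 CPM) and Slurp1 (10555.5) were also highest there, but Slurp1 had 7365 in basal cells. Muc1 and Cldn4 were highest in conjunctival cells, at 162 and 176 CPM against 94.1 and 91.8 in superficial cells. By these CPM of each class's own total, Lypd3 went the other way, with 52.7 CPM in superficial, 121 in basal and 397 in wing cells. Conjunctival cells had the highest means of Krt4 (3237 CPM), Krt13 (6554), Krt19 (3167), Krt7 (617), Krt8 (87.9) and Krt6a (4430, with 4143 in wing cells). Krt18, fixed in the same set, was highest in limbal cells (22.5 CPM) and next in immune cells (14.6), not in conjunctival cells. In limbal cells Krt4 had 688, Krt13 953 and Krt19 415 CPM, against 7.17, 30.2 and 6.36 in basal cells. Mki67 and Top2a, genes of dividing cells, were highest in TAC2 cells, at 354 and 465 CPM, and had 45.9 and 53.2 CPM in limbal cells.

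**Figure D2:**
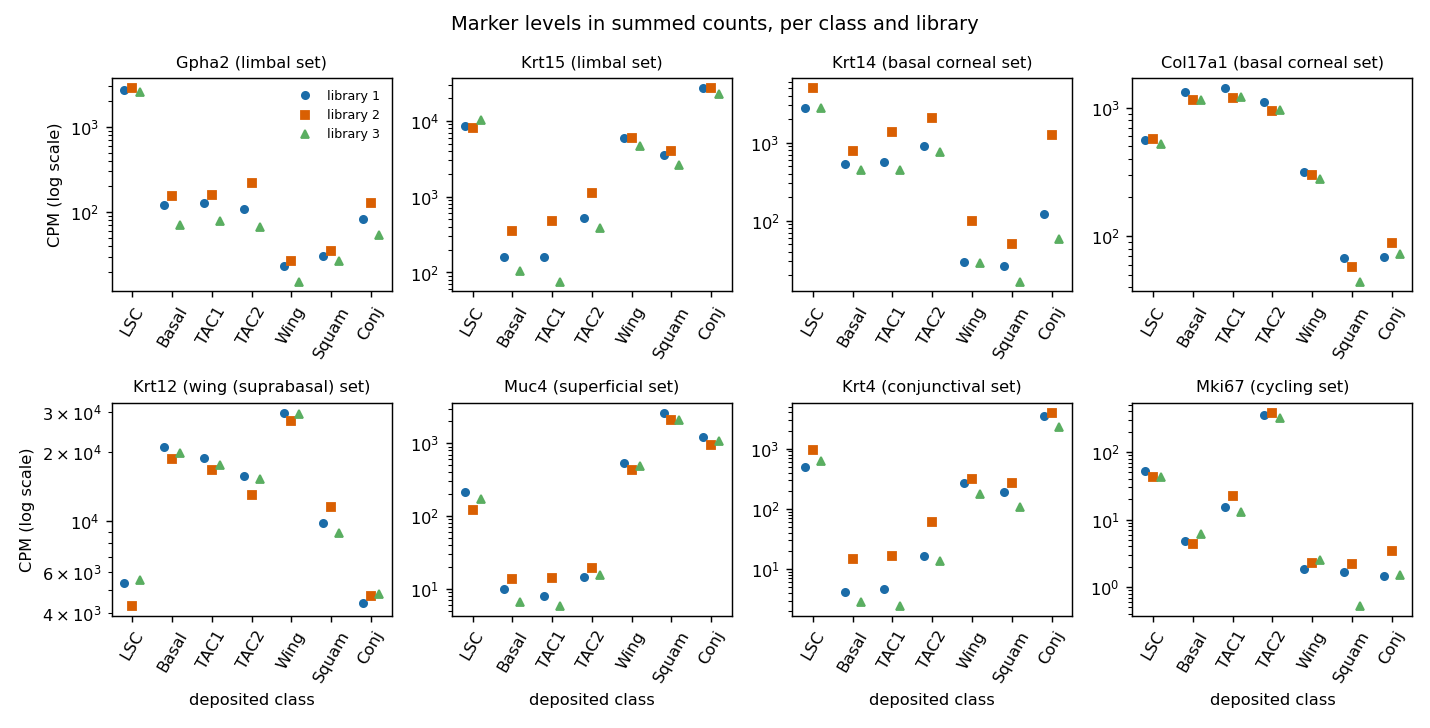
CPM (log axis) of Gpha2, Krt15, Krt14, Col17a1, Krt12, Muc4, Krt4 and Mki67 in each deposited class, with 1 point per library. Gpha2 is highest in limbal cells (mean 2700 CPM), Krt12 in wing cells (28786 CPM) and Krt4 in conjunctival cells (3237 CPM).

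Dividing cells were counted at equal depth, with every cell thinned to 2000 UMIs and shallower cells left out. At that depth 59.5% ± 3.21 (SD, n = 3) of TAC2 cells carried a UMI of Mki67 or Top2a, against 10.2% ± 1.85 of TAC1, 6.60% ± 0.555 of limbal and 1.61% ± 0.215 of basal cells. Wing (0.741% ± 0.0799), superficial (0.716% ± 0.299) and conjunctival cells (0.710% ± 0.0998) had alike low shares, against which the others are set. Whether free RNA, mixed droplets or rare dividing cells gave these low shares was not tested. Without the cells with the highest doublet scores, a choice made after seeing the data, the limbal share was 3.66% ± 1.82, with 2.22, 5.70 and 3.07% in libraries 1, 2 and 3. With all cells, each of these classes differed from basal cells in the same direction in 3 of 3 libraries, with a two-sided exact sign-flip p of 0.25, the smallest that 3 libraries allow. The deposited annotation keeps dividing corneal basal cells in TAC1 and TAC2, so the low basal share follows in part from the labels. The limbal share is thus not shown to exceed that of the whole basal layer. Against basal, TAC1 and TAC2 cells summed, both cell cycle lists were lower in limbal cells, as given below. The number of genes detected in 2000 UMIs was 864 ± 10.6 in basal, 894 ± 7.55 in limbal and 928 ± 8.61 in TAC2 cells. Superficial cells had the fewest, 707 ± 7.20. The difference from basal cells was −157 ± 14.3 genes, lower in 3 of 3 libraries (exact p = 0.25). Before thinning, the median depth was 8417 UMIs in basal, 8690 in limbal, 12428.5 in TAC1, 9702.5 in TAC2, 14083 in wing, 15018.5 in superficial and 13930 in conjunctival cells.

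**Figure D3:**
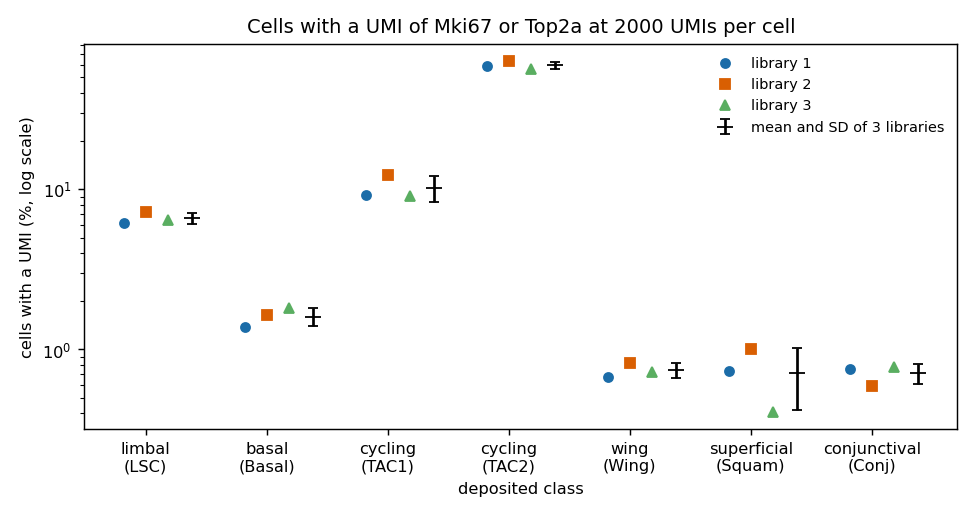
Percent of cells with at least 1 UMI of Mki67 or Top2a at 2000 UMIs per cell (log axis), by class, with points for the libraries and bars for mean ± SD. TAC2 cells lie at 59.5%, limbal cells at 6.60% and basal cells at 1.61%, and wing, superficial and conjunctival cells lie between 0.710 and 0.741%. The annotation keeps dividing corneal basal cells in TAC1 and TAC2, apart from the basal class.

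Limbal cells were compared with basal corneal cells to ask how the epithelium of the limbus, where corneal epithelial stem cells reside, differs from the basal layer of the cornea. Limbal cells had more Id1 and Id3, inhibitors of helix-loop-helix transcription factors and targets of BMP signalling. Id1 was at 330 ± 32.1 against 9.01 ± 0.791 TMM-scaled CPM (SD, n = 3), a log2 fold change of 5.19 ± 0.09 (SE; edgeR adjusted p = 9.4e-42), and Id3 was at 331 ± 108 against 43.4 ± 8.49 (2.91 ± 0.08). The interferon-inducible membrane protein Ifitm3 was higher by 3.19 ± 0.10 (adjusted p = 3.1e-15), at 746 ± 163 against 81.8 ± 20.9 CPM. Ifitm3 was fixed as a limbal marker, so its value describes the class and does not test it. Igfbp2, a binding protein of insulin-like growth factors, was higher by 4.10 ± 0.32, Ly6a, the Sca-1 antigen, by 3.75 ± 0.09, and Hopx, a homeodomain protein without DNA binding, by 4.70 ± 0.09. Among the genes lower in limbal cells were the transmembrane serine protease Tmprss11d (−3.06 ± 0.16, at 73.8 ± 22.8 against 588 ± 46.2 CPM), Dapl1 (880 ± 246 against 3475 ± 614 CPM) and the AP-1 factor Fos (−2.78 ± 0.29). Gyg, the primer of glycogen synthesis (−2.20 ± 0.08), and Ppp1r3c, a glycogen-targeting phosphatase subunit (−2.49 ± 0.13), were lower too. Odc1, the first enzyme of polyamine synthesis, was at −1.86 ± 0.08, and Fam169a, Gmpr, Guca1a and Cyfip2 were at between −2.17 and −1.83. The genes named in this paragraph changed the same way in 3 of 3 libraries. Id1 lies on chromosome 2 from 152736251 to 152737410 on the plus strand, and Gpha2 on chromosome 19 from 6226380 to 6227768 on the plus strand (GRCm38, GENCODE M21).

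In all, 4876 of 12116 genes differed between limbal and basal cells, 2596 higher and 2280 lower in limbal cells, and 13 of the 31 gene lists passed the camera test. The median percentage of mitochondrial UMIs was higher in limbal than in basal cells, at 2.48 against 1.78, 2.19 against 1.76 and 2.91 against 2.09 in libraries 1, 2 and 3. Of the G2 and M phase list 25 of 26 measured genes were higher and 0 lower (median log2 fold change 3.79, camera adjusted p = 2.5e-20), with Hmgb2 at 1.82 ± 0.07, Kif11 at 5.46 ± 0.41 and Ttk at 5.12 ± 0.62. Of the S phase list 21 of 24 were higher and 0 lower, or 22 and 0 adjusted over the list alone (median 1.36, adjusted p = 1.4e-09), with Pcna at 0.58 ± 0.10, Clspn at 3.76 ± 0.34 and E2f8 at 4.33 ± 0.42. With an estimated correlation the adjusted p of each list was 0.614. The deposited annotation keeps dividing corneal basal cells apart from the basal class. Against basal, TAC1 and TAC2 cells summed, an alternative chosen after seeing the data, both lists turned to lower in limbal cells (adjusted p = 6.3e-12 for G2 and M phase and 1.1e-10 for S phase). Of 20 ribosomal protein genes 18 were lower and 0 higher in limbal cells (median −0.24, adjusted p = 1.4e-09, and 0.614 with an estimated correlation), with Rpl13 at −0.49 ± 0.05 and Rps18 at −0.42 ± 0.05.

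The hemidesmosome list had 3 higher and 9 lower of 14 genes in limbal cells (median −0.38, camera adjusted p = 0.00359), with Col17a1 at −1.25 ± 0.07, the integrin Itga2 at −1.80 ± 0.20 and the laminin Lamb1 at −1.79 ± 0.21. Of the list fixed as immediate early and dissociation stress genes 4 were higher and 10 lower of 16, or 4 and 12 adjusted over the list alone (median −1.05, adjusted p = 0.00108), with Junb at −0.91 ± 0.08 and Fosb at −2.51 ± 0.19. The cells were dissociated with trypsin, and whether this gave the changes of that list in any comparison was not tested. For both lists the adjusted p with an estimated correlation was 0.614. The progenitor transcription factors had 11 higher and 8 lower of 20 (median 0.71, adjusted p = 0.0183), with Klf4, a factor of epithelial differentiation, at −1.40 ± 0.07 and Pax6 at −0.37 ± 0.07 beside Id1 and Id3. Antigen presentation genes were higher for 8 of 10, or 9 adjusted over the list alone, with 0 lower (median 0.98, adjusted p = 8.0e-05), among them the class I genes H2-D1 (0.72 ± 0.08) and H2-T23 (1.78 ± 0.12). Of the interferon response genes 7 of 15 were higher and 0 lower (median 1.04, adjusted p = 0.00116). An estimated correlation gave an adjusted p of 0.614 for each of these lists too.

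Lists of barrier and signalling genes were also higher in the limbal class. Tight junction genes were higher for 8 of 14, or 10 adjusted over the list alone, with 0 lower (median 0.63, camera adjusted p = 1.3e-04), with Cldn3 at 5.30 ± 0.16 and Cldn23 at 3.74 ± 0.24. Of the mucin and glycocalyx genes 7 were higher and 1 lower of 10 (median 1.23, adjusted p = 0.00118), with Muc1 at 4.49 ± 0.28. Desmosome and cornified envelope genes had 10 higher and 3 lower of 17 (median 0.37, adjusted p = 0.0122), with Sprr1a at 5.84 ± 0.50 and Tgm1 at 4.50 ± 0.33. Cytokine and alarmin genes had 7 higher and 1 lower of 9 (median 2.38, adjusted p = 4.3e-04), with Cxcl16 at 2.38 ± 0.17 and Il1rn, the interleukin 1 receptor antagonist, at 5.52 ± 0.39. The EGF receptor list had 7 higher and 2 lower of 13 (median 0.34, adjusted p = 0.0417), with the ligands Areg at 6.68 ± 0.35 and Ereg at 5.16 ± 0.42. Each of these lists had an adjusted p of 0.614 with an estimated correlation. Counts adjusted over the list alone are given where they differed from those over all genes tested.

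At 2000 UMIs per cell 24.3% ± 3.21 (SD, n = 3) of limbal cells held at least 3 UMIs of the keratins Krt4, Krt13 and Krt19, fixed as conjunctival markers. The share was 0.130% ± 0.113 in basal, 37.7% in wing, 82.5% in superficial and 93.5% in conjunctival cells, so the set was not specific to the conjunctival class. Without those cells, a choice made after seeing the data, 3693 genes differed, of which 3238 did so in the same direction with all limbal cells. The calls of the tight junction (adjusted p = 0.294), mucin (0.428), desmosome (0.790), hemidesmosome (0.0546) and EGF receptor lists (0.0740) were then lost, and so were those of Hopx, at 2.83 (0.110), and Muc1, at 1.56 (0.0592). Ifitm1 (5.78 ± 0.61, adjusted p = 0.0218), Pglyrp1 (4.74 ± 0.37), Krt6b (4.24 ± 0.47), Psca (3.90 ± 0.44), Asprv1 (3.83 ± 0.45) and Nccrp1 (3.77 ± 0.51) were among the 10 largest higher values above a mean log2 CPM of 5 with markers left out. Without library 1 their values were 5.62, 4.70, 4.17, 3.71, 3.63 and 3.45, close to those with all libraries, but their calls ended, with adjusted p of 0.181, 0.0901, 0.175, 0.153, 0.166 and 0.151. Without library 3 those of Ifitm1 (5.41, 0.194), Psca (3.67, 0.226), Asprv1 (3.59, 0.234) and Nccrp1 (3.57, 0.268) ended. Without the keratin-carrying cells Ifitm1 was at 5.10 (0.0533) and Pglyrp1, Krt6b, Psca, Asprv1 and Nccrp1 at 3.1, 2.19, 2.62, 2.36 and 2.15, with no call. At 2000 UMIs per cell Ifitm1 was at 5.28 (0.0508), and Pglyrp1, Krt6b, Psca and Asprv1 at 3.87, 3.06, 2.55 and 2.60 lost their calls too. Without the library as a block Fosb was at −2.40 (0.0983), and the progenitor factor and EGF receptor lists each had an adjusted p of 0.0643. The EGF receptor list had an adjusted p of 0.0969 without library 2, and without the class markers the hemidesmosome list had 0.196 and the desmosome list 0.0617. Without the cells with the highest doublet scores Psca was at 0.07 (0.746), Nccrp1 at 0.45 (0.0576) and Krt6b at 2.83 (0.0558). With reassigned classes Psca was at 1.13 (0.0512). Nccrp1 lost its call with no filter on low counts (3.73, 0.0624) and with 50% of the UMIs (3.67, 0.0535), as did Asprv1 with no filter (3.79, 0.0503). Sparc, a matricellular protein, was at −0.64 ± 0.12 (adjusted p = 1.0e-05). Its call ended without the keratin-carrying cells (−0.20, 0.261) and without the block (−0.58, 0.172). It also ended at 2000 UMIs per cell (−0.39, 0.191), with equal cell numbers (−0.38, 0.0773) and with reassigned classes (−0.31, 0.163). The count of 4876 fell to 1814 at 2000 UMIs per cell, 2701 with equal cell numbers and 3237 with DESeq2. It was 3038 when classes were reassigned from 50% of each cell's UMIs and tested on the rest, with 2805 genes shared in the same direction, and 3589 with the deposited classes on as many UMIs.

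**Figure D4:**
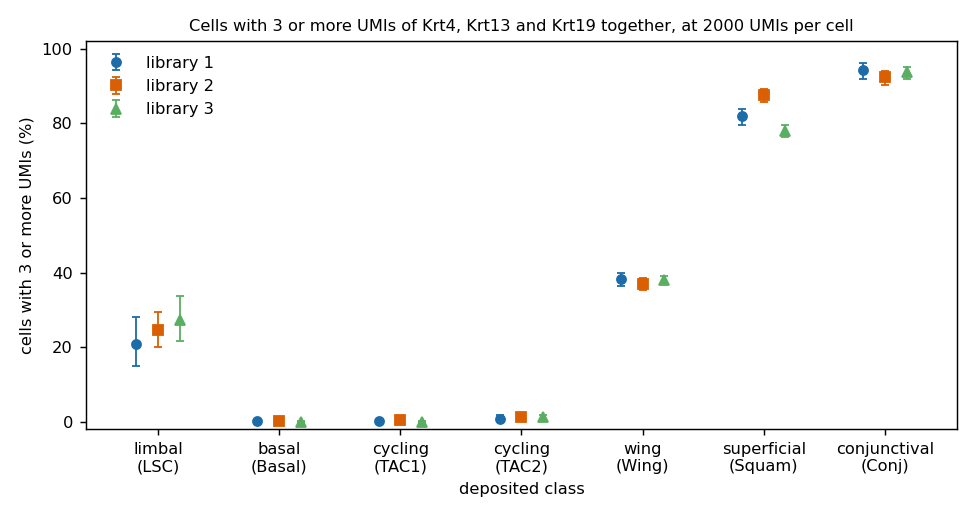
Percent of cells with at least 3 UMIs of Krt4, Krt13 and Krt19 together at 2000 UMIs per cell, by class, with 1 point per library and its exact binomial 95% interval. The mean of limbal cells, 24.3%, lies above that of basal cells (0.130%) and below those of wing (37.7%), superficial (82.5%) and conjunctival cells (93.5%).

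Superficial cells were compared with basal corneal cells to describe the outermost against the innermost layer of the corneal epithelium. Lce3a, a late cornified envelope gene, was at 3656 ± 2295 against 3.18 ± 2.32 CPM, a log2 fold change of 10.23 ± 0.30 (edgeR adjusted p = 1.9e-06). The GPI-anchored surface protein Psca reached 49630 ± 1799 CPM against 57.1 ± 21.5 (9.82 ± 0.29), and Asprv1, a protease that processes filaggrin, 41540 ± 3955 against 59.7 ± 23 (9.51 ± 0.22). The serine protease Prss27 was higher by 9.94 ± 0.18, and Ifit1bl1, AA467197, Cysrt1, Ly6a, Nccrp1 and Hopx by between 8.62 and 10.02. Lower in superficial cells were Gja1, the gap junction protein connexin 43 (−3.82 ± 0.19, at 14.2 ± 3.19 against 200 ± 34.1 CPM), the taurine transporter Slc6a6 (−3.77 ± 0.10), the metallothionein Mt2 (−3.67 ± 0.09), carboxypeptidase E, Cpe (−3.88 ± 0.18), and Dst, a hemidesmosome plakin (−3.41 ± 0.09). Crip1, Gas1 and Lgals7 were lower too, at between −4.13 and −3.39. Ftl1, the ferritin light chain, was at −4.39 ± 0.13, but it has near-identical copies in the genome, so its value is uncertain. The genes named in this paragraph changed the same way in 3 of 3 libraries. Some of the markers fixed as conjunctival were higher in superficial cells too, with Krt13 at 4743 against 30.2 CPM, Krt7 at 524 against 1.89 and Krt19 at 352 against 6.36. Krt12 had 10091 against 19846 CPM. These marker values are scaled to each class's own total, unlike the other CPM of this paragraph. They do not show whether Krt12 was lower on the TMM scale of the fold changes. Whether conjunctival cells lay in the superficial class was not tested. Lce3a lies on chromosome 3 from 92925287 to 92926230 on the minus strand.

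Of 12500 genes tested 10820 differed, 5167 higher and 5653 lower in superficial cells. TMM takes most genes as unchanged, so the split into higher and lower depends in part on the scaling. The desmoplakin gene Dsp was at 0.29 with TMM, but had 358 against 651 CPM of each class's own total. The direction of small changes is therefore uncertain. Barrier genes were higher. All 14 measured tight junction genes were higher (median log2 fold change 3.48, camera adjusted p = 6.7e-06), with Cldn7 at 3.26 ± 0.09 and Cldn23 at 760 ± 87.0 against 1.22 ± 0.291 CPM (9.27 ± 0.15). All 11 mucin and glycocalyx genes were higher (3.62, adjusted p = 1.5e-04), with Muc4 at 3385 ± 398 against 6.74 ± 2.27 CPM, Muc20 at 9.01 ± 0.34 and Lgals3, galectin 3, at 3.62 ± 0.08. Desmosome and cornified envelope genes had 15 higher and 2 lower of 18 (2.15, adjusted p = 4.8e-04), with Ppl at 3.96 ± 0.08 and Cnfn at 10.40 ± 0.15. The adjusted p of these lists was 0.614 with an estimated correlation. Genes that anchor the basal layer were lower. The hemidesmosome list had 2 higher and 11 lower of 14 (−2.85, adjusted p = 0.00503), with Col17a1 at −3.29 ± 0.10 and Itgb4 at −4.05 ± 0.10. All 9 matrix genes were lower (−2.98, adjusted p = 0.00200), with Sparc at −4.20 ± 0.15, the keratoepithelin gene Tgfbi at −2.81 ± 0.08 and fibronectin, Fn1, at −2.98 ± 0.09. All 20 ribosomal protein genes were lower (−1.49, adjusted p = 4.0e-07), with Rpl13 at −1.92 ± 0.08 and Rpl3 at −2.13 ± 0.08. The hemidesmosome, matrix and ribosomal lists had an adjusted p of 0.614 with an estimated correlation. Beside these, the median percentage of mitochondrial UMIs was lower in superficial than in basal cells, at 1.04 against 1.78, 0.942 against 1.76 and 1.13 against 2.09 in libraries 1, 2 and 3, and the nuclear RNA Malat1, chosen after its value was seen, had 35250 ± 6024 against 11468.5 ± 564 CPM.

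Defence genes were higher in superficial cells. Interferon response genes had 13 higher and 2 lower of 16 (median 3.32, camera adjusted p = 0.00288), with Ifitm1 at 8.56 ± 0.40 and the transcription factor Irf1 at 5.77 ± 0.10. All 9 antigen presentation genes were higher (2.78, adjusted p = 1.7e-04), with H2-D1 at 3.94 ± 0.10 and the immunoproteasome subunit Psmb8 at 5.61 ± 0.13. Cytokine and alarmin genes had 10 higher and 3 lower of 13 (5.07, adjusted p = 0.0354), with Il18 at 4.93 ± 0.09, Tnf at 9.86 ± 0.18 and Cxcl2 at 10.26 ± 0.28. Antimicrobial genes had 7 higher and 1 lower of 8 (7.26, adjusted p = 0.0254), with Defb1 at 6.62 ± 0.16 and lactoferrin, Ltf, at 9.86 ± 0.16. For these 4 lists the adjusted p with an estimated correlation was 0.614. Lipid and cholesterol synthesis genes had 11 higher and 2 lower of 16 (1.36, adjusted p = 0.0243, and 0.720 with an estimated correlation), with Insig1 at 5.54 ± 0.09 and Fdps at 2.74 ± 0.13. Counts adjusted over the list alone were the same for the 11 lists. Without the class markers the antimicrobial list had an adjusted p of 0.0537, and without the block it had 0.0664 and the cytokine list 0.0809.

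**Figure D5:**
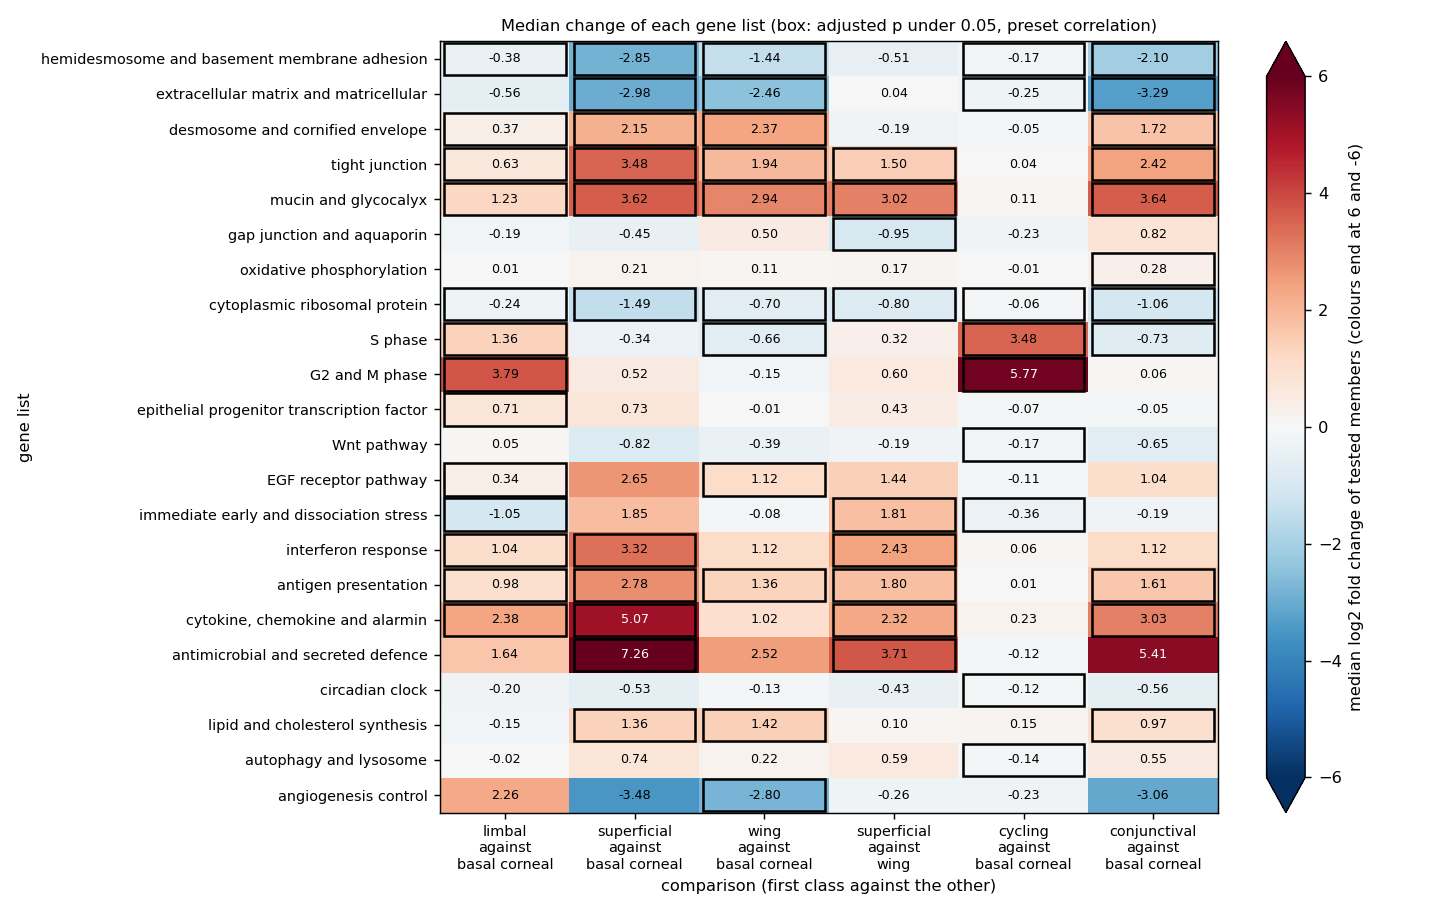
Median log2 fold change of each gene list (vertical) in each of the 6 comparisons (horizontal), as colour, with a box around those with a camera adjusted p under 0.05 at the preset correlation. Tight junction genes are boxed in 5 comparisons, with medians of 0.63 to 3.48, and ribosomal protein genes in all 6, with medians of −1.49 to −0.06. No list passed with an estimated correlation, a test that could hardly pass any list here.

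Wing cells were compared with basal corneal cells to describe the suprabasal layers against the basal layer. Wing cells had more Akr1b7, an aldo-keto reductase, at 441 ± 35.4 against 4.33 ± 1.27 CPM (log2 fold change 6.68 ± 0.10, edgeR adjusted p = 1.5e-12), and more Hopx, at 2124 ± 298 against 22.5 ± 3.03 CPM (6.56 ± 0.14). Krt6b, a keratin of stratified and wounded epithelium, was at 3103 ± 165 against 39.1 ± 14.8 CPM (6.36 ± 0.34, adjusted p = 0.00123). Pglyrp1, Asprv1, Cysrt1, Nccrp1, Psca, Ifitm1 and Cstdc5 were higher by between 4.88 and 5.80. Phgdh, the first enzyme of serine synthesis, was lower, at −3.59 ± 0.05, with 20.4 ± 3.12 against 245 ± 24.1 CPM. The laminin receptor Bcam (−3.39 ± 0.06), the lipid carrier Apoe (−3.21 ± 0.11), Igfbp5 (−2.80 ± 0.05) and Slc6a6 (−2.79 ± 0.05) were lower too, and Cpe, Crip1, Antxr1 and Wfdc2 were at between −3.26 and −2.88. Ftl1 was at −3.69 ± 0.06, with the same uncertainty from its copies. The genes named in this paragraph changed the same way in 3 of 3 libraries. Akr1b7 lies on chromosome 6 from 34412334 to 34423142 on the plus strand.

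Of 13172 genes tested 10221 differed, 5117 higher and 5104 lower in wing cells. Lipid and cholesterol synthesis genes were higher for 15 of 16, with 0 lower (median 1.42, camera adjusted p = 2.1e-06), among them Fdps (2.40 ± 0.06, at 973 ± 41.5 against 185 ± 17.3 CPM), Sqle (2.48 ± 0.05) and Scd2 (1.44 ± 0.06). Desmosome and cornified envelope genes had 16 higher and 1 lower of 19 (2.37, adjusted p = 2.3e-06), with desmoplakin, Dsp, at 1.29 ± 0.05 and plakoglobin, Jup, at 1.43 ± 0.05. Tight junction genes were higher for 13 of 14, with 0 lower (1.94, adjusted p = 9.3e-06), with Cldn7 at 2.24 ± 0.05 and Cldn3 at 5.83 ± 0.15. Mucin genes had 9 higher and 1 lower of 10 (2.94, adjusted p = 7.5e-04), with Muc4 at 5.77 ± 0.29. The EGF receptor list had 10 higher and 2 lower of 13 (1.12, adjusted p = 0.0377), with Areg at 7.05 ± 0.17 and the receptor Erbb3 at 1.21 ± 0.05. Antigen presentation genes had 11 higher and 1 lower of 12 (1.36, adjusted p = 6.2e-04), with H2-D1 at 1.22 ± 0.05. These 6 lists had an adjusted p of 0.614 with an estimated correlation. Cd74, the class II invariant chain, was at 3.85 ± 0.25, at 3.56 ± 3.34 against 0.244 ± 0.245 CPM, and turned to −1.14 with reassigned classes. In immune cells Cd74 had 21159 CPM.

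All 9 matrix genes were lower in wing cells (median −2.46, camera adjusted p = 1.7e-04), with Sparc at −4.28 ± 0.06, at 2.35 ± 0.554 against 45.8 ± 12 CPM, and Tgfbi at −0.75 ± 0.05. The hemidesmosome list had 1 higher and 12 lower of 14 (−1.44, adjusted p = 7.5e-05), with Col17a1 at −1.85 ± 0.05, Itgb4 at −3.46 ± 0.06 and Itga2 at −4.05 ± 0.10. All 20 ribosomal protein genes were lower (−0.70, adjusted p = 4.0e-07), with Rpl3 at −0.97 ± 0.05. The angiogenesis list had 1 higher and 5 lower of 6 (−2.80, adjusted p = 0.0237), with Timp3 at −3.58 ± 0.07, the thrombospondin Thbs1 at −3.45 ± 0.13 and Vegfb at −2.49 ± 0.06. An estimated correlation put the adjusted p of these 4 lists at 0.614. S phase genes had 2 higher and 15 lower of 24 (−0.66, adjusted p = 0.0149, and 0.695 with an estimated correlation), with Dut, a dUTPase, at −2.43 ± 0.06 and E2f8 at 1.61 ± 0.30. Counts adjusted over the list alone were the same for the 11 lists of wing cells. The S phase list had an adjusted p of 0.0537 without the block.

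Superficial cells were then compared with wing cells, for the last step of differentiation. Chac1, an enzyme that degrades glutathione, was at 488 ± 71.3 against 3.03 ± 0.413 CPM (log2 fold change 7.33 ± 0.09, edgeR adjusted p = 2.1e-17). The antimicrobial S100 protein S100a7a was higher by 6.88 ± 0.16, the serine protease Prss22 by 6.21 ± 0.08 and Dusp5, a phosphatase of ERK kinases, by 5.74 ± 0.07. AA467197, Ly6a, Tspan1, Ifit1bl1 and Sdcbp2 were higher by between 5.57 and 8.31. Lce3a was at 8.39 ± 0.92 (adjusted p = 0.0117), and its call ended without library 2 (8.24, 0.109). The hyaluronan receptor Cd44 was lower in superficial cells, at −2.84 ± 0.07, with 18.1 ± 3.22 against 130 ± 19.4 CPM. The retinol-metabolising dehydrogenase Adh7 (−2.38 ± 0.06), the fatty acid binding protein Fabp5 (−2.30 ± 0.15), tissue factor, F3 (−2.23 ± 0.07), the glutathione transferase Gsta2 (−2.16 ± 0.06) and Dapl1 (−2.67 ± 0.06) were lower, as were Chl1, Trpm3, Dst and Lima1, at between −2.29 and −2.22. Each of these genes changed the same way in 3 of 3 libraries. Sparc did not pass, with a log2 fold change of 0.07 ± 0.21 (adjusted p = 0.769), at 1.69 ± 0.794 and 1.57 ± 0.359 CPM.

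Of 12818 genes tested 10215 differed, 4856 higher and 5359 lower in superficial cells than in wing cells. Immediate early and dissociation stress genes were higher for 14 of 16, with 0 lower (median 1.81, camera adjusted p = 1.1e-04), with Junb at 1.66 ± 0.06, Jund at 2.11 ± 0.06 and Dusp1 at 4.70 ± 0.14. Whether the dissociation of the cells gave this was not tested. Interferon response genes had 14 higher and 1 lower of 15 (2.43, adjusted p = 6.2e-05), with Isg15 at 4.65 ± 0.11 and Irf1 at 4.41 ± 0.07. Antimicrobial genes were higher for 7 of 8, with 0 lower (3.71, adjusted p = 0.00186), with Defb1 at 2.50 ± 0.06 and Ltf at 8.01 ± 0.10. Cytokine and alarmin genes had 9 higher and 3 lower of 13 (2.32, adjusted p = 0.0368), with Il1a at 2.32 ± 0.16 and Tnf at 8.65 ± 0.12. The adjusted p with an estimated correlation was 0.614 for these 4 lists. Antigen presentation genes had 9 higher and 3 lower of 12 (1.80, adjusted p = 0.00951, and 0.695 with an estimated correlation), with H2-D1 at 2.73 ± 0.07. The class II gene H2-Ab1, at −3.14 ± 0.43, had 9795 CPM in immune and 1.34 ± 1.41 in wing cells, with 2.96 in library 2 against 0.613 and 0.433 in libraries 1 and 3, and lost its call without the block (−3.23, 0.0536). Rsad2 was at 5.12 ± 1.12, and its call ended without library 2 (5.90, adjusted p = 0.113), without library 3 (5.70, 0.153) and with no filter on low counts (5.06, 0.0624). The call of Cxcl2, at 8.63 ± 0.93, ended without library 1 (8.45, 0.0970).

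All 14 tight junction genes were higher in superficial than in wing cells (median 1.5, camera adjusted p = 2.2e-05), with Tjp1 at 3.00 ± 0.06 and Cldn23 at 4.55 ± 0.09. Mucin and glycocalyx genes had 8 higher and 3 lower of 11 (3.02, adjusted p = 0.0191), with Muc4 at 3.22 ± 0.07 and the mucin glycosyltransferases St3gal1 at 8.05 ± 0.15 and C1galt1 at 3.99 ± 0.11. The gap junction and aquaporin list had 1 higher and 7 lower of 9 (−0.95, adjusted p = 0.0378), with Gja1 at −1.66 ± 0.14 and Aqp3 at −0.95 ± 0.07, and with the water channel Aqp5 at 1.04 ± 0.07. Of 20 ribosomal protein genes 18 were lower and 0 higher (−0.80, adjusted p = 2.1e-06), with Rpl3 at −1.15 ± 0.06. For each of these 4 lists an estimated correlation gave an adjusted p of 0.614. Counts adjusted over the list alone were the same for the 9 lists of this comparison. The mucin list had an adjusted p of 0.106 without the class markers, and the cytokine list had 0.0799 without the block.

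Cycling cells, TAC1 and TAC2 summed, were compared with basal corneal cells to see what changes with cell division besides the cell cycle genes. Stmn1, a microtubule-destabilising protein, was at 665 ± 143 against 40.4 ± 9.54 CPM (log2 fold change 4.04 ± 0.04, edgeR adjusted p = 1.0e-24). Tyms, the thymidylate synthase, was higher by 3.04 ± 0.05, Atad2 by 2.98 ± 0.05 and Hmgb2 by 3.04 ± 0.09. The histone genes Hist1h1b (4.70 ± 0.05), Hist1h2ap (3.95 ± 0.12) and Hist1h2ae (3.42 ± 0.07) were higher, but have near-identical copies, so their values are uncertain. The kinase subunits Cks1b (3.19 ± 0.16) and Cks2 (3.15 ± 0.32) and the histone variant H2afx (3.17 ± 0.23) kept their size without library 2, at 3.24, 3.27 and 3.30, but lost their calls, with adjusted p of 0.0553, 0.143 and 0.0997. Lower values were small. The histone demethylase Kdm5b was at −0.63 ± 0.05 (adjusted p = 3.8e-09) and the small heat shock protein Hspb1 at −0.53 ± 0.04, at 1558 ± 27.3 against 2246 ± 108 CPM. Tcim, Pnrc1, Neat1, Wnt2, Plin2, Btg2, Aldoa and Gyg were at between −0.61 and −0.51. All of these genes changed the same way in 3 of 3 libraries. Hist1h1b lies on chromosome 13 from 21779883 to 21780625 on the minus strand.

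Of 12523 genes tested 5406 differed, 2867 higher and 2539 lower in cycling cells. All 26 G2 and M phase genes were higher (median 5.77, camera adjusted p = 3.2e-28), with Kif11 at 7.54 ± 0.13, and so were all 24 S phase genes (3.48, adjusted p = 3.2e-28), with Pcna at 1.90 ± 0.04. With an estimated correlation both had an adjusted p of 0.614. Immediate early and dissociation stress genes were lower for 13 of 16, with 0 higher (−0.36, adjusted p = 5.9e-06), with Junb at −0.39 ± 0.04. Of the hemidesmosome genes 0 were higher and 10 of 14 lower, or 11 adjusted over the list alone (−0.17, adjusted p = 1.8e-04), with the laminin Lama3 at −0.41 ± 0.04 and Dst at −0.31 ± 0.04. The Wnt list had 0 higher and 8 lower of 14 (−0.17, adjusted p = 0.0149), with Wnt6 at −0.33 ± 0.06. Matrix genes had 1 higher and 6 lower of 9 (−0.25, adjusted p = 0.0233), with Nid1 at −0.40 ± 0.07 and Sparc at −0.21 ± 0.04. Autophagy and lysosome genes had 1 higher and 9 lower of 14, or 1 and 10 adjusted over the list alone (−0.14, adjusted p = 0.0254), with the protease Ctsl at −0.33 ± 0.04. The circadian list had 0 higher and 6 lower of 14 (−0.12, adjusted p = 0.0298), with Cry2 at −0.33 ± 0.06. An estimated correlation gave these 6 lists an adjusted p of 0.614. Ribosomal protein genes had 0 higher and 2 lower of 20, or 0 and 1 adjusted over the list alone (−0.06, adjusted p = 0.0354, and 0.805 with an estimated correlation).

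Of the lists lower in cycling cells, the matrix (adjusted p = 0.0535), autophagy (0.0517), circadian (0.0969) and ribosomal lists (0.171) lost their calls without library 2, the circadian list without library 1 (0.0571) and the ribosomal list without library 3 (0.196). Without the library as a block 1589 genes differed, 1313 higher and 276 lower, 2766 at 2000 UMIs per cell and 2741 with DESeq2. The calls of Tcim, Neat1, Plin2, Btg2, Aldoa, Gyg, Dst, Lama3, Nid1, Wnt6, Cry2 and Sparc were lost without the block with little change in their values, such as −0.60 for Tcim, −0.31 for Dst and −0.20 for Sparc. The Wnt (adjusted p = 0.0644), autophagy (0.0673), matrix (0.0763), ribosomal (0.165) and circadian lists (0.344) lost theirs too. At 2000 UMIs per cell the calls of Nid1 (adjusted p = 0.440) and Sparc (0.204) were lost.

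Conjunctival cells were compared with basal corneal cells to describe the epithelium that borders the limbus. Upp1, a uridine phosphorylase, was at 696 ± 130 against 1.99 ± 1.27 CPM (log2 fold change 8.51 ± 0.24, edgeR adjusted p = 3.6e-06). The peptidoglycan recognition protein Pglyrp1 was higher by 7.89 ± 0.38, Akr1b7 by 7.87 ± 0.25, the ectonucleotidase Enpp3 by 7.76 ± 0.19 and Krt6b by 7.26 ± 0.38. Hopx, Ifit1bl1, Prss27 and Nccrp1 were higher by between 6.61 and 7.35. Ifitm1 was at 7.72 ± 0.46 (adjusted p = 0.00339) and lost its call without library 1 (7.64, 0.0573). Slc6a6 was lower, at −4.05 ± 0.10, with 41.2 ± 10.6 against 678 ± 124 CPM. Cpe (−4.04 ± 0.13), Mt2 (−3.77 ± 0.12), Igfbp5 (−3.57 ± 0.09), the hedgehog coreceptor Gas1 (−3.56 ± 0.09), Fam169a and the tensin Tns4 (−3.48 ± 0.08) were lower as well. Ftl1 was at −4.41 ± 0.12, again uncertain for its copies. Crip1, at −4.03 ± 0.41, lost its call without library 3 (−3.93, adjusted p = 0.0797). The genes named in this paragraph changed the same way in 3 of 3 libraries. Upp1 lies on chromosome 11 from 9118103 to 9136170 on the plus strand.

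Of 12244 genes tested 9471 differed, 4572 higher and 4899 lower in conjunctival cells, and 6193 did at 2000 UMIs per cell. All 14 tight junction genes were higher (median 2.42, camera adjusted p = 2.1e-06), with Cldn7 at 2.70 ± 0.08 and Cldn3 at 7.43 ± 0.12. Mucin and glycocalyx genes had 10 higher and 1 lower of 11 (3.64, adjusted p = 4.4e-04), with Muc1 at 8.19 ± 0.13 and Muc4 at 7.10 ± 0.39. Desmosome and cornified envelope genes had 15 higher and 1 lower of 17 (1.72, adjusted p = 2.9e-05), with Dsp at 0.80 ± 0.06 and Tgm1 at 6.25 ± 0.14. Antigen presentation genes were higher for 8 of 9, with 0 lower (1.61, adjusted p = 3.0e-04), with H2-D1 at 2.36 ± 0.07 and the peptide transporter Tap1 at 2.91 ± 0.08. Cytokine and alarmin genes had 7 higher and 1 lower of 9, or 8 and 1 adjusted over the list alone (3.03, adjusted p = 0.0149), with Il1rn at 7.88 ± 0.19 and Il33 at 6.07 ± 0.21. These 5 lists had an adjusted p of 0.614 with an estimated correlation. Lipid synthesis genes had 13 higher and 1 lower of 16 (0.97, adjusted p = 0.00116, and 0.645 with an estimated correlation), with Fdps at 2.86 ± 0.09. Oxidative phosphorylation genes had 16 higher and 1 lower of 20, or 16 and 2 adjusted over the list alone (0.28, adjusted p = 0.0149, and 0.723 with an estimated correlation), with Ndufa4 at 2.32 ± 0.07. The call of this list ended without library 1 (0.0571).

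All 9 matrix genes were lower in conjunctival cells (median −3.29, camera adjusted p = 6.0e-04), with Sparc at −4.71 ± 0.14, at 1.65 ± 0.579 against 43.6 ± 11.6 CPM, and Fn1 at −3.11 ± 0.09. Sparc lies on chromosome 11 from 55394500 to 55423183 on the minus strand. The hemidesmosome list had 2 higher and 12 lower of 14 (−2.10, adjusted p = 8.1e-04), with Col17a1 at −3.66 ± 0.10, Itga2 at −4.61 ± 0.20 and Itga3 at −4.14 ± 0.17. All 20 ribosomal protein genes were lower (−1.06, adjusted p = 1.7e-09), with Rpl13 at −1.54 ± 0.05 and Rps18 at −1.42 ± 0.05. The adjusted p of these lists with an estimated correlation was 0.614. S phase genes had 1 higher and 15 lower of 24 (−0.73, adjusted p = 0.0298, and 0.695 with an estimated correlation), with Dut at −2.72 ± 0.12, Pcna at −0.42 ± 0.09 and E2f8 at 2.21 ± 0.40. Without the block its adjusted p was 0.107.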

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

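Leaving out the highest doublet scores, limbal cells with conjunctival keratins, the joint reference of basal, TAC1 and TAC2 cells, TAC1 or TAC2 alone and 50% of the UMIs with the deposited classes were chosen after seeing the data, and the other alternatives before. The 6 counts of changed genes stayed within 1.5 times under DESeq2 size factors, no filter, the highest doublet scores left out and 50% of the UMIs. Without 1 library in turn they ranged from 3458 to 4293 (limbal), 10187 to 10740 (superficial), 9571 to 10218 (wing), 9480 to 9832 (superficial against wing), 3942 to 5132 (cycling) and 8574 to 9180 (conjunctival), and the lists called from 69 to 71. The limbal count was 1814 at 2000 UMIs per cell, 2701 with 163 cells per class and library and 3038 with reassigned classes, each of which leaves fewer UMIs, and 3237 with DESeq2 as the test. The cycling count was 1589 without the library block, 2766 at 2000 UMIs and 2741 with DESeq2, and the conjunctival count 6193 at 2000 UMIs. Without the replicate block the totals of the other 5 comparisons stayed within 1.5 times, but the lower genes of limbal cells went from 2280 to 1499, and TAC1 alone went from 5113 to 1298 genes and TAC2 alone from 5927 to 2630. The lower genes of limbal cells also fell without library 1, to 1517. For DESeq2 and the block the cause was not tested. Like TMM, DESeq2 size factors take most genes as unchanged. Where most genes differed, as in superficial, wing and conjunctival cells, they do not test how far small changes depend on the scaling. Of the 64 lists called 0 were called with an estimated correlation, which could hardly pass any list, 60 without the class markers and 52 without the block. Of all 186 tests fry called 127, among them 62 of the 64. The planned removal of called doublets gave no value, since Scrublet called 0 cells, and the planned comparison of each class with the others was not needed.

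Against basal, TAC1 and TAC2 cells summed, the cell cycle lists turned to lower in limbal cells, since dividing cells then are in the reference. Of the 13 lists called against basal cells alone, 10 kept their call and direction. G2 and M phase had an adjusted p of 6.3e-12 and S phase of 1.1e-10, and Pcna was at −0.69, E2f8 at −0.49, Clspn at −1.13, Hmgb2 at −0.42, Kif11 at −1.20 and Ttk at −1.09, of which E2f8 (adjusted p = 0.0653) and Kif11 (0.205) did not pass. In limbal cells Cldn7 turned to −0.034 at 2000 UMIs, −0.027 with reassigned classes and −0.41 without keratin-carrying cells. Lgals3 turned to −0.12 with reassigned classes and −0.12 without keratin-carrying cells. With reassigned classes Il18 turned to −0.013 in limbal and Cd74 to −1.14 in wing cells. The cause was not tested for these. Of 337 named genes past the threshold, 305 kept their call without the block, 318, 322 and 325 without libraries 1, 2 and 3, and 337 with DESeq2 size factors.

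The share of cells with Mki67 or Top2a and the number of genes follow the depth by construction. At 1000 UMIs the share was 4.55% in limbal, 1.01% in basal, 6.16% in TAC1, 42.6% in TAC2, 0.449% in wing, 0.243% in superficial and 0.465% in conjunctival cells. Unthinned it was 19.4, 5.57, 31.4, 80.7, 6.24, 4.11 and 4.24%. Genes per cell at 1000 UMIs were 535.5 in limbal, 521.3 in basal, 526.9 in TAC1, 558.1 in TAC2, 529.0 in wing, 426.6 in superficial, 521.1 in conjunctival and 541.4 in immune cells, and unthinned 2655, 2396, 2862, 2856, 3420, 2569, 3072 and 992.4. Without the highest doublet scores the Mki67 or Top2a share was 3.66% in limbal and 0.559% in conjunctival cells, and the basal share of cells 23.7%. The cause of these 3 was not tested.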

Other observations

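The tests of free RNA, mixed droplets, conjunctival cells, depth, cytoplasmic loss and damaged cells and the splits were chosen after the result was seen, and that of the time of day before.

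The 114 immune cells carried class II antigen presentation genes, with Cd74 at 21159 CPM, H2-Ab1 at 9795 and H2-Aa at 6949, beside Tyrobp at 2420, Fcer1g at 1871, Cd52 at 1739 and the leukocyte antigen Ptprc at 399. Other cell types left little RNA of the markers in the table. Those not in it, among them Col1a1, Kera and Hbb-bs, could not be counted, so the sums do not show how much RNA such cells left. Over all cells the melanocyte markers in the table summed to 2.75 CPM (3 of 5 in the table), Schwann cell markers to 1.34 (3 of 5) and corneal endothelial markers to 3.22 (3 of 4). Pericyte markers summed to 1.30 (2 of 4), keratocyte markers to 0.322 (2 of 7), vascular endothelial markers to 0.261 (1 of 5) and erythroid markers to 0.600 (2 of 4). Goblet cell markers summed to 7.19 CPM (3 of 5) and epidermal markers to 34.9. Agr2, a goblet cell gene, had 43.7 CPM in limbal and 43.5 in conjunctival cells.

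The 2 transit-amplifying classes differed in the phase of the cell cycle they carried. The S phase list summed to 2070 ± 132 CPM (SD, n = 3) in TAC1, 1572 ± 324 in TAC2, 600 ± 204 in limbal and 314 ± 52.9 in basal cells. The G2 and M phase list summed to 6921 ± 824 CPM in TAC2, 820 ± 40.5 in TAC1, 1235 ± 234 in limbal and 292 ± 21.1 in basal cells.

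Part of the limbal class carried keratins fixed as conjunctival markers, with at least 3 UMIs of Krt4, Krt13 and Krt19 at 2000 UMIs in 24.32% of limbal cells. The share was 0.130% ± 0.113 of basal cells, which argues against free RNA, as that would reach both alike. But 37.7% of wing and 82.5% of superficial cells carried them too, so they do not point to the conjunctival class alone. Whether conjunctival cells lay in the wing and superficial classes was not tested. The keratin-carrying limbal cells, 34, 85 and 60 in libraries 1, 2 and 3, had 175.6 ± 33.4 CPM of Mki67 plus Top2a. At 2000 UMIs 14.7, 9.41 and 10% of them carried a UMI of either, so few cells gave this value. It lay above the 55.9 ± 13.9 of the other limbal cells and the 4.21 ± 1.58 of conjunctival cells. This argues against droplets with a limbal and a conjunctival cell of average Mki67 and Top2a as the whole cause. In the same way it argues against such a limbal cell with a wing or superficial cell (Mki67 at 2.20 and 1.46 CPM, Top2a at 2.54 and 2.73). The Gpha2 of the keratin-carrying limbal cells was 10.67 ± 0.933 times that of conjunctival cells, but the limbal label was made on the same counts. Of them 55.7% had a UMI of Gpha2, against 89.0% of the other limbal and 13.7% of conjunctival cells. From 50% of their UMIs 78 of the 737 limbal cells were reassigned to the conjunctival class. Conjunctival cells as a part of the keratin-carrying cells therefore stay open. Of these cells 35.1% were among the highest doublet scores, against 13.4% of the other limbal cells, so droplets that include a dividing cell stay open too, and no biological explanation was tested.

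The share of TAC1 cells was lower in library 3, of whose basal, TAC1 and TAC2 cells 18.06% (exact 95% interval 17.1 to 19.0) had at least 3 UMIs of the S phase list at 2000 UMIs, against 30.3 and 33.4% in libraries 1 and 2, and as depth was equal this argues against lower depth as the cause. For the G2 and M phase list the share was 23.5% in library 3 and 20.8 and 24.5% in libraries 1 and 2, so that share was not lower. In these classes the clock genes of library 3 differed from libraries 1 and 2 by a median absolute log2 of 0.9225, against 0.123 between libraries 1 and 2, with Arntl at 2.31 and Per2 at −2.17. In wing, limbal, conjunctival and superficial cells the difference was smaller, at 0.556, 0.438, 0.335 and 0.320, against 0.162, 0.293, 0.220 and 0.253. There Arntl was at 1.35, 2.63, 1.13 and 0.62, and Per2 at −1.16, −0.41, −0.23 and −0.18. Why the classes differed in this was not tested. A different time of day at collection may be behind the lower share of S phase cells, since the cell cycle of the corneal epithelium follows the clock. Library 1, with a TAC1 share of 14.1%, was from males like library 3, and libraries 2 and 3 were 1 week apart in age, so sex alone does not set library 3 apart and age does so little, but age, its 7 mice and batch were not tested and cannot be told apart from the time of day.

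Superficial cells had more Malat1, a nuclear RNA, with 35250 CPM and a log2 ratio of 1.61 ± 0.247 to basal cells, and Neat1 was at 0.80 ± 0.142. Malat1 was chosen after its value was seen. A loss of cytoplasmic RNA would raise all nuclear RNAs if their production stayed the same. The nuclear RNA Kcnq1ot1 had a log2 ratio of −4.085 ± 0.0167 and Xist in library 2 of −3.14. But 10820 of 12500 genes differed between these classes, so both RNAs may be lower by changes of their own. A loss of cytoplasmic RNA therefore stays open. Shallow or damaged cells with few UMIs are argued against, since the superficial cells with the most UMIs had a median Malat1 2.706 ± 0.437 times that of basal cells. Other technical explanations and a biological explanation were not tested.

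Each comparison rests on 3 sums against 3, which make 10 splits. The real split was the only 1 of the 10 with as many changed genes in each of the 6 comparisons, with 4876 (limbal), 10820 (superficial), 10221 (wing), 10215 (superficial against wing), 5406 (cycling) and 9471 (conjunctival), against a highest other count of 0. Every other split puts sums of both classes on each side, so the class difference enters the spread of the model and leaves few calls possible. Some of these splits also put both sums of a library on the same side, which breaks the pairing. The counts of 0 therefore lend no weight to the real split, and the splits are too few for a share under 0.05.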
